A study of Mus musculus with 2 samples.

How the data were processed

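H3K27me3 ChIP-seq was measured in liver of mouse embryos of day 13.5 (strain B6NCrl, embryos of both sexes pooled per the labels), in a single group of 2 biological replicates. H3K27me3 is trimethylation of lysine 27 on histone H3, the modification that Polycomb repressive complexes place on silenced developmental genes. ChIP-seq enriches chromatin fragments with an antibody and counts them by sequencing against control chromatin.

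The authors deposited 4 peak lists in narrowPeak format on the mm10 assembly, per the text files that accompany them. There is 1 list for each replicate, 1 list called on both replicates pooled, and 1 list named replicated peaks that was derived from the other 3. Replicate 1 combined 2 technical replicates and replicate 2 had 1, per the labels. The list of replicate 2 derives from its alignments and 1 control file, and the list of replicate 1 derives from its alignments and 2 control files, of which 1 is the control of replicate 2, per the deposited text files. The controls behind the lists therefore differed between the replicates. The aligner, the peak caller, its threshold and the rule behind the replicated list are not given in the sources used here. Each peak carries a fold enrichment over control, which is a linear ratio set by the authors' peak caller. Each peak also carries the authors' −log10 p and −log10 q. The lowest −log10 p lay between 2.01 and 2.03 in the 4 lists. These values were used only to describe, rank or filter peaks within a list, and as log2 fold for peaks matched between the replicates. The deposited lists hold no read counts, so the depth of each library is unknown and no limit of detection can be given. Intervals given for shares of peaks are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

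All 58587 replicated peaks had the start and end of a pooled peak. A rule by which a pooled peak and a peak of each replicate overlap over 50% of either peak was tested on the files. All 45557 pooled peaks that met it were in the replicated list, and they made up 77.8% of that list. The other 22.2% met a criterion that is not given in the sources used here. Of the replicated peaks, 9.85% shared no base with a peak of replicate 1 and 12.1% shared none with a peak of replicate 2, so that a replicated peak need not be a peak of both single lists.

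Genes, transcripts and sequence came from the GRCm38 genome, which is mm10, with the GENCODE M21 annotation. As a check of the coordinates, 99.9% of 27907 annotated start codons read ATG on the genome, and no peak ended beyond its chromosome. The gene universe was 21938 protein-coding genes on chromosomes 1 to 19, X and Y. A promoter was the gene's 5′ end ± 1 kb, and it was called marked when a peak overlapped it by at least 1 bp. A single peak of replicate 2 on an unplaced contig was left out. Fold values given for a gene are those of the highest peak that touches its promoter, so a gene can carry the value of a peak that belongs mainly to its neighbour.

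The replicates were compared by the share of each list's peaks with at least 50% of their length covered by the other list. The expected share came from 1000 circular shifts of the peaks within each chromosome (permutation test, one-sided). Bases in promoters, exons, introns and intergenic sequence, taken in that order, were compared with 1000 shifts (permutation test, two-sided), and GC share and CpG observed over expected ratio with 100 shifts. Promoter CpG ratios used ± 500 bp. Membership of 24 gene lists was tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Genes are not biological replicates, so the text gives the counts from each replicate's own list for the 24 gene lists, but not for the gene families among the additional observations. Peaks 3 kb or less apart were merged to domains. The gene lists, tests and most alternatives were fixed before the data were examined. The alternatives restricted to autosomes or to the X chromosome were added afterwards.

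Genes named were those with a start site in the 10 longest domains, the 10 with the strongest promoter peaks (1 name per peak), and for each list up to 3 marked members with the highest fold and the first 3 unmarked members, or all of the smaller side where it had 5 or fewer. The 5 promoters per replicate with the strongest peaks that lacked a peak in the other replicate, and any unmarked Hox gene, were named as well. Crlf1, whose start site lies in another gene's peak, Myod1 and Ezh1 were chosen after results were seen. So were the genes and families named only among the additional observations.

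The alternatives were a −log10 q of at least 2, the pooled list, each replicate's own list alone, the stronger 50% of peaks, other overlap rules, promoter windows of ± 500 bp and ± 2 kb, 50% of the window covered, any annotated start site, merging within 1 kb or 10 kb, 10000 random lists matched on promoter CpG ratio, and 10000 rotations of the list labels along the genome. The procedures were tested on simulated data. Planted overlaps of 20, 40 and 60% were recovered as 20.0, 39.7 and 60.0%, on lists of 2948 to 2971 simulated peaks. These recovered shares were corrected for the expected share, while the shares of real peaks below are given uncorrected. With 1000 peaks per list, 3 of 100 pairs of unrelated lists passed the threshold. A planted promoter share of 50% was recovered as 50.8% over 1975 simulated peaks, with the same correction. Simulated peaks lay at random on 2 chromosomes, apart from the planted ones, so they give no error rate for clustered peaks. With the 21938 genes marked at random at 27%, 0.083% of list tests passed. Of 8 lists with 75% of members marked, 98.1% of tests passed. Simulated marks were set gene by gene, without shared peaks or CpG dependence. They therefore give no error rate for lists of neighbouring genes or of unusual CpG ratio. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The data hold 1 group, so no comparison between conditions was made.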

Results

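The data map H3K27me3 in liver of mouse embryos at embryonic day 13.5, a stage at which the liver is also the main site of blood formation. There was 1 group with 2 biological replicates, each a pool of embryos of both sexes. Replicate 1 held 126354 peaks and replicate 2 held 107850 on assembled chromosomes. The pooled list held 121362 peaks and the replicated list 58587. Peaks covered 62.8 Mb in replicate 1 and 59.5 Mb in replicate 2, with a mean of 61.2 ± 2.28 Mb (SD, n = 2), which is 2.31 ± 0.086% of the sequenced genome. Replicated peaks covered 57.4 Mb or 2.17% of the genome. Most peaks were short, with a median width of 253 bp in replicate 1, 262 bp in replicate 2 and 457 bp in the replicated list, and the longest replicated peak spanned 53495 bp. Values below are from the replicated list unless a replicate is named.

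All 39 Hox genes, the homeobox regulators of the body axis, had a marked promoter, and so no unmarked Hox gene remained in any of the 4 clusters. After merging of peaks within 3 kb there were 20263 domains, of which 2020 were 10 kb or longer, and 66.3% of these long domains held a protein-coding start site. The longest domain covered Hoxc13 to Hoxc4 on chromosome 15 (mm10, 102894737 to 103150587, 256 kb), and 91.3% of it lay inside peaks. The next were the Hoxa cluster with Evx1, 5730596B20Rik and Gm28308 on chromosome 6 (52146426 to 52329232, 183 kb) and Hoxb9 to Hoxb1 on chromosome 11 (96228395 to 96385557, 157 kb). The Hoxd cluster with Evx2 and Gm28230 on chromosome 2 (74642726 to 74772994, 130.3 kb) was shorter than a domain on chromosome 13. Hoxb13 lay in a separate domain, outside the 10 longest. The highest fold at a Hox promoter was 23.2, at Hoxd13, Hoxd12 and Hoxd11, which shared a value because a single peak spanned them. Median fold at the promoters was 17.5 for Hoxa, 18.5 for Hoxb, 16.1 for Hoxc and 19.5 for Hoxd.

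**Figure D1:**
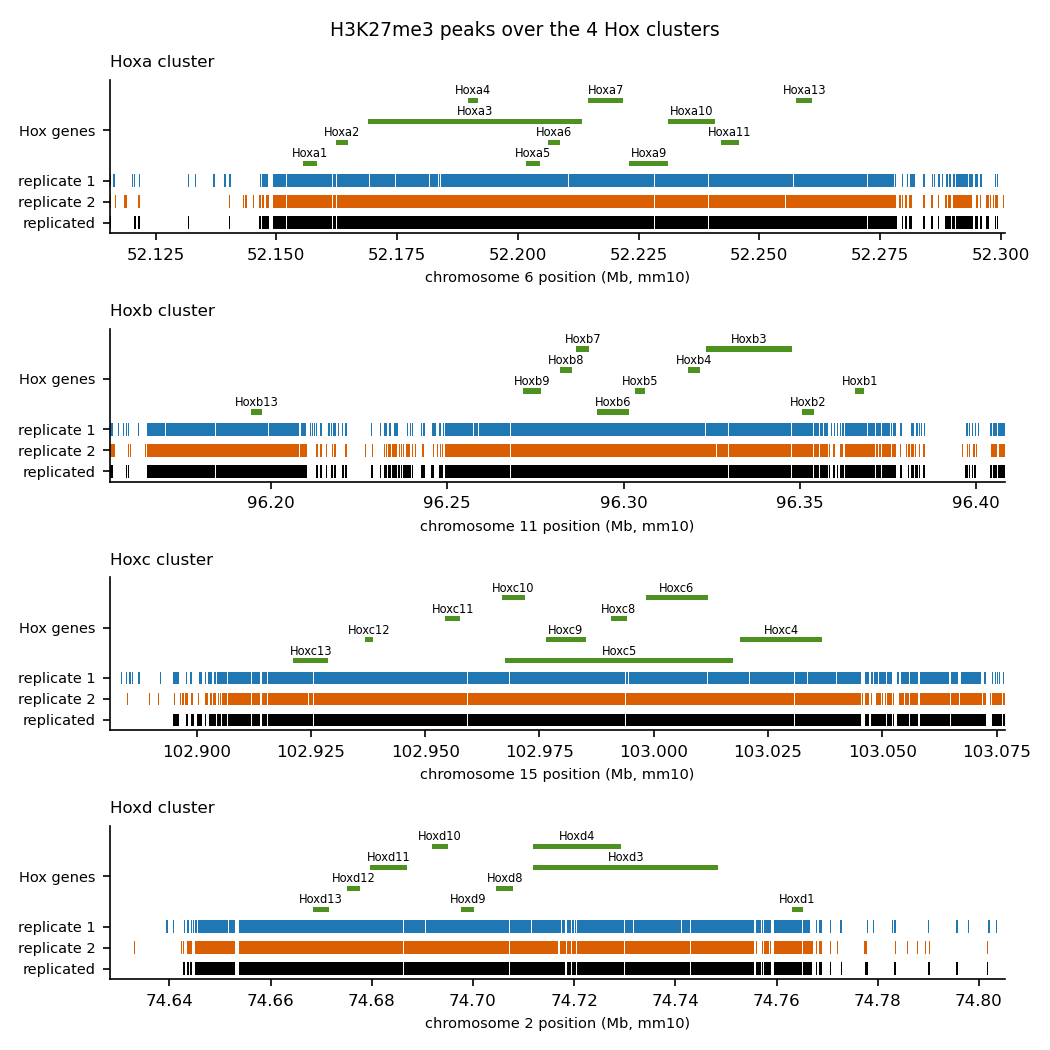
Map of H3K27me3 peaks over the 4 Hox clusters. The x axes give mm10 position in Mb; bars show peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (black), with Hox genes in green on 4 levels for legibility. Peaks in both replicates run across each cluster, and Hoxb13 sits apart from Hoxb9 in its own stretch of peaks.

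The fourth longest domain had no protein-coding start site. It spanned 136 kb of chromosome 13 (45198803 to 45334752), and peaks covered 46.4% of it in replicate 1 and 60.8% in replicate 2. The other domains among the 10 longest held Rhcg on chromosome 7 (128 kb), Cacna1g, Spata20 and Epn3 on chromosome 11 (109 kb), 6430628N08Rik and Dmbx1 on chromosome 4 (97.4 kb), Uncx on chromosome 5 (97.3 kb) and Lhx2 on chromosome 2 (89.97 kb). Rhcg encodes an ammonium transporter, Cacna1g a T-type calcium channel, and Dmbx1, Uncx and Lhx2 are homeobox genes. The count of domains rested on the list. There were 42234 in replicate 1 and 34036 in replicate 2 (38135 ± 5797, SD, n = 2), while the longest domain was alike, 263 and 261 kb.

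The strongest promoter peak was at Wnt3a, a secreted Wnt ligand, with a fold of 30.3 on chromosome 11 (59285884 to 59295251). That peak ranked 2 in each replicate, with folds of 25.5 and 30.7. It was followed by a 19.4 kb peak over Tmem59l, which also covers the start site of Crlf1 (fold 29.2), and by Onecut3 (28.9), Pou3f1 (28.9), Nkx1-1 (28.2), Ccdc177 (27.9), Tlx2 (27.1), Sox1 (26.7), Mafa (26.2) and Foxe1 (26.1). Onecut3, Pou3f1, Nkx1-1, Tlx2, Sox1, Mafa and Foxe1 encode transcription factors of neural, pancreatic or thyroid development. The 10 peaks were 9.37 to 20.8 kb wide, and each ranked within the first 21 of replicate 1 and the first 18 of replicate 2.

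At promoters, 5950 of 21938 protein-coding genes (27.1%) were marked. Replicate 1 marked 6724 and replicate 2 marked 6553, a mean of 30.3 ± 0.55% (SD, n = 2), and 5915 promoters had a peak in both. On the X chromosome, replicate 1 marked 200 promoters and replicate 2 marked 294 of 948. With autosomal genes alone, 5760 of 20807 promoters (27.7%) were marked.

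Of the 24 gene lists, 13 were marked more often than other genes, 2 less often, and 9 passed in neither direction. All 32 neural transcription factors were marked, led by Sox1 (26.7), Olig2 (26.0) and Dlx1 (23.0), at 3.70 times the share of other genes (Fisher's exact test, adjusted p = 5.53e-18). For the 39 Hox genes the ratio was also 3.70 (Fisher's exact test, adjusted p = 8.69e-22). They lie in only 5 domains, and Fisher's exact test counts neighbours under a shared peak as independent. Rotation of the list labels along the genome, which keeps neighbours together, gave an adjusted p of 0.00053 (permutation test). Limb and skeletal patterning factors were marked at 24 of 25 promoters, led by Foxc1 (23.3), Six1 (23.2) and Foxd1 (22.6), and Runx2, the osteoblast regulator, was the exception (Fisher's exact test, adjusted p = 2.16e-12). With the pooled list all 25 of these promoters were marked, that of Runx2 included. Endoderm factors of organs other than liver were marked at 15 of 16 promoters, led by Foxe1, Insm1 (21.9) and Cdx2 (20.7), and Isx was unmarked (Fisher's exact test, adjusted p = 1.28e-07). Secreted signalling factors were marked at 27 of 29, with Fgf8 (22.3) and Fgf3 (21.8) behind Wnt3a, and Fgf10 and Cer1 were unmarked (Fisher's exact test, adjusted p = 6.39e-13). In these 5 lists both replicates gave the same counts as the replicated list.

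Heart and skeletal muscle factors were marked at 14 of 17 promoters, led by Hand1 (19.5), Nkx2-5 (18.8) and Tbx1 (18.4) (Fisher's exact test, adjusted p = 9.83e-06), with 15 in replicate 1 and 14 in replicate 2. The 3 unmarked members, Myf5, Myf6 and Myog, are myogenic regulators, but so is Myod1, which was marked. Neuronal function genes were marked at 23 of 28, led by Cacna1g (21.4), the vesicular GABA transporter Slc32a1 (18.95) and Rbfox3 (17.9) (Fisher's exact test, adjusted p = 7.89e-09), with 24 and 23 in the replicates. Gad1, Scn2a, Cacna1a, Nrxn1 and Th were unmarked.

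Hepatic transcription factors were marked at 13 of 17 promoters, 2.82 times the share of other genes (Fisher's exact test, adjusted p = 8.51e-05), with 14 of 17 in each replicate. Cebpa, a regulator of hepatocyte and myeloid genes, had a fold of 20.2, Onecut2 17.7 and Hhex, which acts in early liver budding, 16.7. Hnf4a, Nr1h4, Nr0b2 and Xbp1 were unmarked. Of the secreted proteins of fetal hepatocytes, 4 of 22 were marked, namely Vtn (12.4), Rbp4 (6.998), Trf (3.31) and Apoe (2.12), and Alb, Afp and Apoa1 were not (Fisher's exact test, ratio 0.67, adjusted p = 0.47). The replicates marked 5 and 4, and the ratio to CpG-matched random lists was 0.99. Of the adult hepatic metabolism genes, Sds (4.22) and Hpd (2.13) were marked out of 24, while Cyp1a2, Cyp2e1 and Cyp3a11 were not (Fisher's exact test, ratio 0.31, adjusted p = 0.058). Replicate 1's list alone marked 4 of these genes (ratio 0.54, Fisher's exact test, adjusted p = 0.24). Replicate 2's list alone marked 2, a lower share than in other genes (ratio 0.28, Fisher's exact test, adjusted p = 0.035).

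Erythroid genes were marked at 6 of 31 promoters, 7 in replicate 1 and 5 in replicate 2 (Fisher's exact test, ratio 0.71, adjusted p = 0.44). Their ratio to CpG-matched random lists was 1.01. Ank1, encoding the membrane skeleton protein ankyrin, had a fold of 23.3, Add2 10.4 and the embryonic globin gene Hba-x 5.73, while the erythroid regulators Gata1, Klf1 and Nfe2 were unmarked. Progenitor and myeloid genes were marked at 10 of 26, led by Gfi1 (19.7), Gata2 (19.6) and Flt3 (17.98), and Spi1, Runx1 and Mecom were unmarked (Fisher's exact test, ratio 1.42, adjusted p = 0.23), with 13 and 11 in the replicates. Lymphoid genes were marked at 13 of 23, led by Pax5 (19.9), Eomes (19.2) and Bcl11b (18.8), and Cd4, Cd8a and Zap70 were unmarked (Fisher's exact test, ratio 2.09, adjusted p = 0.0075), with 14 in each replicate. The lymphoid call was lost with the stronger 50% of peaks (ratio 1.63, Fisher's exact test, adjusted p = 0.18).

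The endothelial, the stellate and mesothelial, and the biliary lists were each marked at over 50% of their promoters. Endothelial genes were marked at 10 of 18, led by Sox18 (18.4), Flt1 (16.6) and Sox7 (15.9), with Cdh5, Tek and Tie1 unmarked (Fisher's exact test, ratio 2.05, adjusted p = 0.021), with 11 in each replicate. That call was lost with the pooled list (ratio 1.78, Fisher's exact test, adjusted p = 0.062). Stellate and mesothelial genes were marked at 11 of 19, led by Wt1 (19.3), Pdgfra (16.1) and Ngfr (12.9), with Hgf, Col3a1 and Acta2 unmarked (Fisher's exact test, ratio 2.14, adjusted p = 0.012), with 12 and 13 in the replicates. Biliary genes were marked at 8 of 12, led by Hnf1b (16.3), Epcam (15.5) and Sox4 (13.4), and Krt19, Spp1, Notch2 and Aqp1 were unmarked (Fisher's exact test, ratio 2.46, adjusted p = 0.0089), with 9 in each replicate.

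None of the 20 cell cycle promoters, such as Mki67, Top2a and Ccna2, was marked in the replicated list or in either replicate (Fisher's exact test, adjusted p = 0.0076). Olfactory receptor genes were marked at 13 of 1093, at most 3.79-fold, at Olfr65, followed by Olfr95 (3.60) and Olfr64 (3.21) (Fisher's exact test, ratio 0.042, adjusted p = 1.91e-129). The single lists marked 31 in replicate 1 (ratio 0.088) and 23 in replicate 2 (0.067). Against CpG-matched random lists, which were marked at 8.29%, the ratio was 0.14, and with the stronger 50% of peaks it was 0.011. With 50% of the window covered no olfactory receptor promoter was marked, and with the pooled list the ratio was 0.073. Rotation of the list labels along the genome gave an adjusted p of 0.00053 for these genes (permutation test). Housekeeping genes were marked at 3 of 25, namely Rpl3 (4.38), Eef1a1 (2.82) and Pgk1 (2.53), and Actb, Gapdh and Tbp were not (Fisher's exact test, ratio 0.44, adjusted p = 0.15). The promoter of Pgk1, on the X chromosome, had no peak in replicate 1 and 170 bp of peak in replicate 2. Replicate 1's list alone marked 2 housekeeping genes, a lower share than in other genes (ratio 0.26, Fisher's exact test, adjusted p = 0.022). Replicate 2's list alone marked 4 (ratio 0.54, Fisher's exact test, adjusted p = 0.23). Imprinted genes were marked at 18 of 30 promoters, led by Igf2 (20.0), Dio3 (19.8) and Ascl2 (19.7), with Ins2, Igf2r and Slc22a18 unmarked (Fisher's exact test, ratio 2.22, adjusted p = 0.00056), and the replicates marked 20 and 18.

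Of the 7 CDK inhibitor genes, Cdkn2a (16.3), Cdkn1a (12.8), Cdkn1c (12.7) and Cdkn2b (8.85) were marked and Cdkn1b, Cdkn2c and Cdkn2d were not (Fisher's exact test, ratio 2.11, adjusted p = 0.13), as in each replicate. Polycomb component genes were marked at 8 of 20, led by Cbx8 (19.1), Cbx4 (16.2) and Pcgf2 (12.1) (Fisher's exact test, ratio 1.48, adjusted p = 0.24), with 8 and 9 in the replicates. Of the complex that writes the mark, Ezh2, Eed and Suz12 were unmarked, while Ezh1, its other catalytic member, was marked. Of 16 germline genes, Tdrd1 (4.28) and Dnmt3l (3.82) were marked and Dazl, Ddx4 and Sycp1 were not (Fisher's exact test, ratio 0.46, adjusted p = 0.29), but the single lists marked 5 in replicate 1 (ratio 1.02) and 6 in replicate 2 (ratio 1.26). Clustered protocadherin genes were marked at 20 of 57, led by Pcdhgc3 (13.5), Pcdhga11 (9.51) and Pcdhgb7 (9.51), with Pcdha1, Pcdha2 and Pcdha3 unmarked (Fisher's exact test, ratio 1.29, adjusted p = 0.23), with 21 and 23 in the replicates. Their ratio to CpG-matched random lists was 0.97.

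**Figure D2:**
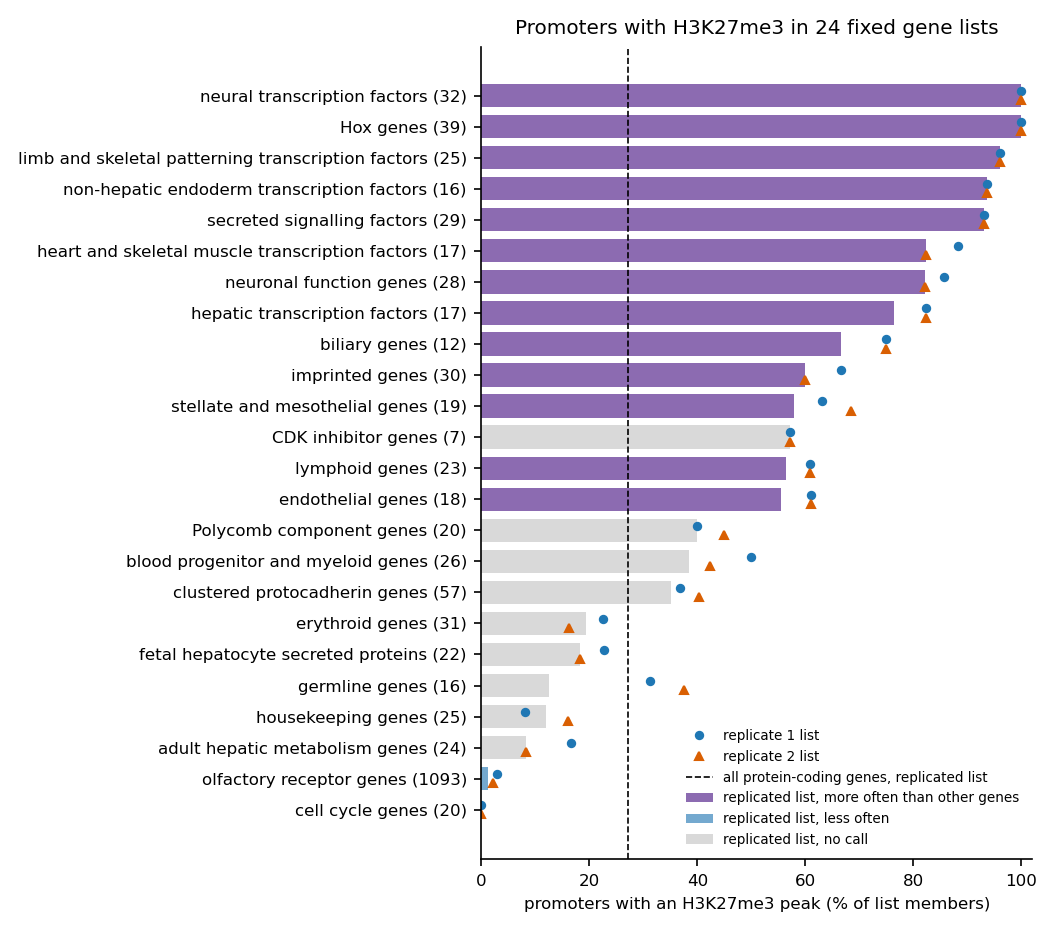
Share of promoters with an H3K27me3 peak (x axis, % of list members) in 24 gene lists, with the number of genes in parentheses. Bars give the replicated list, coloured by the Fisher's exact test call, points give each replicate's own list, and the dashed line marks the 27.1% of all protein-coding genes. Regulators of neural, axial and limb development stand at 96.0% or more, cell cycle and olfactory receptor genes at or near 0.

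Promoters made up 15.03% of the bases in peaks, 8.68 times the share under shifts (permutation test, p = 0.002, the smallest these shifts can give). The single lists gave folds of 7.69 and 8.33 (8.01 ± 0.46, SD, n = 2). Exons outside promoters held 11.1% of bases, 2.34 times the expected share (permutation test, p = 0.002). Introns held 39.9% and intergenic sequence 34.0%, which were 0.93 and 0.67 times the expected shares (permutation test, p = 0.008 and 0.002).

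Peaks were richer in GC and CpG than shifted positions. Their GC share was 51.6% against a mean of 42.1% under shifts, and the CpG observed over expected ratio was 0.34 against 0.19 (permutation test, p = 0.0198 for each, the smallest 100 shifts can give). The median promoter CpG ratio was 0.63 at marked and 0.46 at unmarked promoters. Marking did not rise steadily with CpG ratio. With promoters in 10 deciles of CpG ratio, 3.97% were marked in the lowest, 46.5% in decile 5 and 26.5% in the highest. Decile 5 also had the highest share in each replicate (50.2 and 50.5%).

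**Figure D3:**
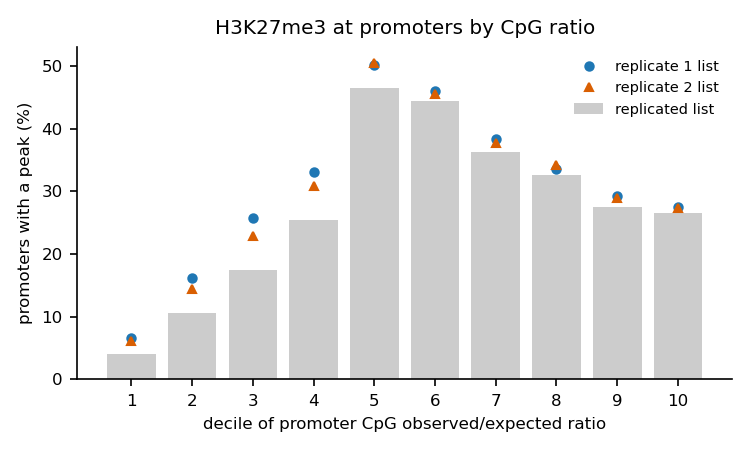
Share of promoters with an H3K27me3 peak (y axis, %) by decile of promoter CpG observed over expected ratio (x axis, 1 lowest). Bars give the replicated list and points the single replicates. The share peaks at 46.5% in decile 5 and is 26.5% in decile 10.

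Between the replicates, 36.1% of replicate 1 peaks (95% interval 35.9 to 36.4%) were shared with replicate 2, against 2.47% expected, and 40.4% of replicate 2 peaks (40.1 to 40.7%) were shared with replicate 1, against 2.496% expected (permutation test, p = 0.001 for each, the smallest 1000 shifts can give). By bases the overlap was larger, 62.5% of replicate 1 and 65.9% of replicate 2. Over 48883 peaks matched between the replicates, log2 fold correlated with a Pearson's r of 0.845 and a Spearman's rho of 0.540, across peaks, which are not independent replicates. Of the pooled peaks, 48.3% (48.0 to 48.6%) were in the replicated list. That share was 13.3% in the weakest decile by fold and 99.9% in the strongest.

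**Figure D4:**
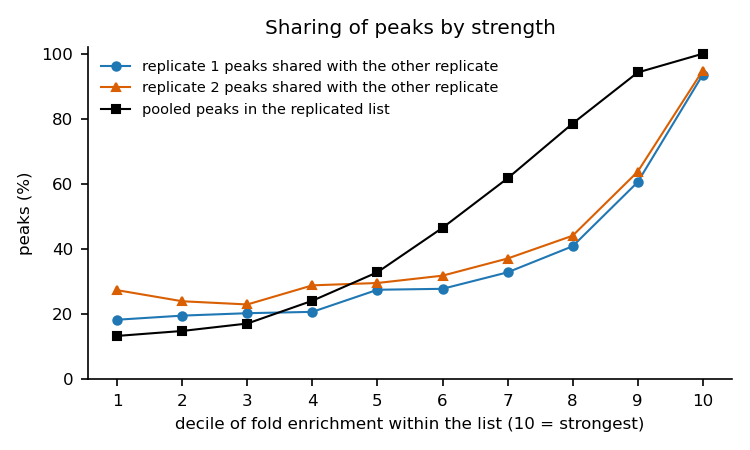
Percent of peaks (y axis) by decile of fold enrichment within each list (x axis, 10 strongest). Lines give peaks of replicate 1 (circles) and replicate 2 (triangles) shared with the other replicate, and pooled peaks in the replicated list (squares). Sharing reaches 93.5 and 94.8% in the strongest decile of the single lists and 99.9% of the pooled list.

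The strongest promoter peaks in replicate 1 alone were at Large2 (fold 10.6), Tulp4 (4.20), D130043K22Rik (4.16), Ube2j2 (4.03) and Tap2 (3.99), and in replicate 2 alone at Racgap1 (14.97), Psmb3 (9.55), Lmtk2 (6.09), Gap43 (4.72) and C1qa (4.40). At 8 of these 10 the other replicate had a peak between 1.03 and 1.26 kb from the start site, just outside the promoter window. The exceptions were Tap2, at 3.78 kb, and D130043K22Rik, at 51.2 kb.

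The chromosomes differed in coverage by the mark in both replicates. Chromosome 11 carried the most, 47.9 ± 3.15 kb of peaks per Mb (SD, n = 2), followed by chromosome 19 with 37.1 ± 2.20, while chromosome 3 carried 14.3 ± 0.90. No list held a peak on the Y chromosome. Replicate 2 had 0.90 to 0.93 times the coverage of replicate 1 on each autosome, and 2.75 times its coverage on the X chromosome. The X chromosome held 3474 peaks and 7.70 kb per Mb in replicate 1, and 10197 peaks and 21.2 kb per Mb in replicate 2. Relative to the autosomes, X coverage was 0.30 in replicate 1, 0.90 in replicate 2 (0.60 ± 0.43, SD, n = 2) and 0.44 in the replicated list, where 31.6% of X peaks shared no base with a replicate 1 peak. On the X chromosome 11.5% of replicate 2 peaks were shared with replicate 1, against 43.4% on autosomes. In the other direction, 51.1% of replicate 1 peaks on X were shared with replicate 2, against 35.7% on autosomes.

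**Figure D5:**
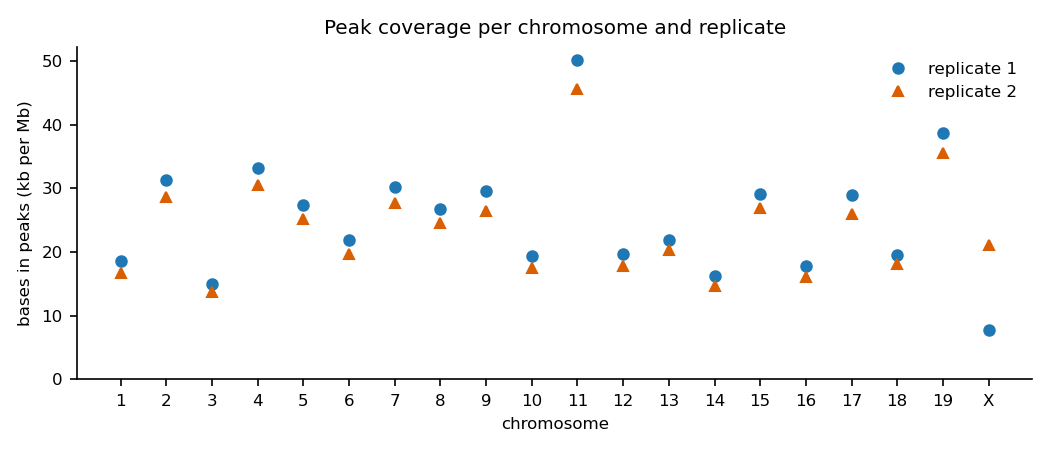
Bases in peaks (y axis, kb per Mb of sequenced chromosome) for each chromosome (x axis), with circles for replicate 1 and triangles for replicate 2. Replicate 1 is slightly higher on each autosome, and replicate 2 is higher on X, 21.2 against 7.70 kb per Mb.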

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

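The alternatives on autosomes or the X chromosome were chosen after the data were seen. Over 38 results and 373 alternatives, 342 kept direction and side of the threshold or stayed within their spread. Direction turned in 5, all in gene lists without a call: germline genes (ratio 1.001 with the pooled list, 1.02 to 1.26 in single replicates' lists), and, against CpG-matched lists, erythroid genes (1.01) and clustered protocadherins (0.97). The 50 alternatives on overlap, annotation and sequence kept their calls, promoter folds lay between 7.27 and 10.3, and marked promoters between 4416 and 6851. For 18 of the 24 gene lists the presence or absence of a call held in all 12 alternatives. The endothelial call was lost with the pooled list (ratio 1.78) and a 2 kb window (1.83), and the lymphoid call with the stronger 50% of peaks (1.63) and with 50% of the window covered (1.73). Calls were gained for adult hepatic metabolism with the stronger 50% of peaks (0.17), for housekeeping genes likewise (0.17), for CDK inhibitors with a 2 kb window (2.36) or any start site (2.37), and for progenitor and myeloid genes with any start site (1.66). Single replicates' lists gave ratios of 0.28 to 0.54 for adult hepatic metabolism and 0.26 to 0.54 for housekeeping genes. The correlation of matched peaks was 0.893 at a −log10 q of at least 2, 0.965 for −log10 p, 0.849 on autosomes and 0.681 on X. The replicated share was 58.0% at a −log10 q of at least 2. X over autosome coverage ranged from 0.30 to 0.90 between the single lists. Domains numbered 33471 in the pooled list, 34036 to 42234 in single lists and 13326 with the stronger 50% of peaks. Domains of 10 kb or more numbered 3420 in the pooled list, 2671 to 3068 in single lists, 1228 with the stronger 50% of peaks, and 1195 or 3418 when merged within 1 or 10 kb. The causes of these shifts were not tested. No paired analysis was possible because the data hold a single group. Depth is unknown, so it cannot be said which weak peaks it limits.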

Other observations

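The tests of escape genes and of control libraries were set before the values they measure were seen, and the tests of depth, CpG content, blood cells, weak calls and split domains, the gene family tests, and the descriptions of domains, non-coding promoters and X windows were chosen after results were seen. Grouping protein-coding genes by the letters of their symbol gave 268 families of at least 10 genes, of which 42 were marked more often and 30 less often than other genes (Fisher's exact test, Benjamini-Hochberg adjustment over 268). All 19 Wnt ligand genes were marked (adjusted p = 2.24e-09, Fisher's exact test), as were 18 of 20 Sema guidance genes, 12 of 12 Pcdh genes outside the clusters, 9 of 10 Fzd receptor genes, 31 of 45 Col collagen genes and 15 of 19 Adamts protease genes. Marks were found at 13 of 14 Htr serotonin receptor genes and 15 of 17 Syt synaptotagmin genes. Of the transcription factors, 14 of 14 Nkx, 17 of 19 Sox and 11 of 13 Tbx genes were marked. Of 394 Zfp zinc finger genes, 61 (15.5%) were marked, a lower share than in other genes (adjusted p = 1.33e-06, Fisher's exact test). Of the clustered protocadherins, 0 of 22 Pcdhb genes (adjusted p = 0.0073, Fisher's exact test) were marked, against 9 of 12 Pcdhga genes (adjusted p = 0.0047, Fisher's exact test), which passed in the other direction. The Pcdha genes, with 0 of 12 marked, did not pass (adjusted p = 0.099, Fisher's exact test). Families marked less often also included Hist histone genes (1 of 67), Rpl ribosomal protein genes (2 of 54), Vmn vomeronasal receptor genes (0 of 331), Prl prolactin family genes (0 of 25) and Mup urinary protein genes (0 of 22). Family members that are neighbours are not independent. The families were not matched on promoter CpG ratio, and only 3.97% and 10.5% of all promoters in CpG deciles 1 and 2 were marked. A low share in a family therefore need not go beyond its CpG content.

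The 136 kb domain on chromosome 13 without a protein-coding start site covers the start sites of the long non-coding genes Gm47448 (45235635) and Gm34466 (45267711). The domain of Rhcg also covers Mir9-3hg, the host gene of the microRNA Mir9-3 (79505264 to 79505353 on chromosome 7). Of 5854 lincRNA promoters, 760 (13.0%) were marked, and 10.2% of those over 5 kb from a protein-coding start site. In windows of 5 Mb along the X chromosome, replicate 2 had more bases in peaks in 28 and fewer in 2 (ratios 0.957 and 0.935) of the 30 windows with any peak, and 3 windows held none. Both replicates were highest in the window from 100 to 105 Mb, which holds the start site of Xist (103483254), with 46.1 kb per Mb in replicate 1 and 137 in replicate 2.

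The X chromosome held 10197 peaks in replicate 2 and 3474 in replicate 1, and greater depth or a looser threshold in replicate 2 is argued against by the autosomes, where replicate 2 had 0.795 times the peaks of replicate 1. A control with less X coverage would raise every X peak by a common factor. Matched peaks were compared by the log2 ratio of their folds, replicate 2 over replicate 1. In the strongest 25% (by mean log2 fold of both replicates) the median was 0.33 on X and 0.17 on autosomes. The shift of X against autosomes was 0.16 (95% bootstrap interval 0.13 to 0.18, 257 X pairs). The bootstrap resampled peaks and does not cover variation between replicates. From the weakest 25% up, the other shifts were 0.15 (0.050 to 0.16), 0.12 (0.11 to 0.20) and 0.25 (0.23 to 0.31). The second of these lies just under the interval of the strongest (0.1249 against a lower bound of 0.1254). The third lies above that interval, and its own interval overlaps no other. Every shift was above 0, but a single common factor does not describe the third. More of the mark on X in replicate 2 would also give shifts above 0, so their sign does not favour a control difference. A control difference stays open as a candidate explanation, without a test of how many peaks it would add. More cells with an inactive X in replicate 2 may also raise X peaks, but a peak in replicate 2 alone was found at 6 of 25 broadly expressed X genes and 1 of 10 genes known to escape inactivation (Fisher's exact test, one-sided, p = 0.335), and so few genes leave it open. The labels do not give the share of each sex in a pool, and the design has no group to test a biological explanation.

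Hepatic transcription factors were marked at 13 of 17 promoters in a tissue that holds hepatocytes, and high CpG content alone is argued against, since the share was 2.51 times that of CpG-matched random lists. If the mark came from the blood cells of the tissue, transcription factors used by erythroid cells could be expected to lack it, and 1 of 7 (Tal1) was marked, with a median promoter CpG ratio of 0.32 against 0.59 for the hepatic factors. That test had 3 versions, each set after results were seen: all members (Fisher's exact test, one-sided, p = 0.0088), 16 hepatic genes within the CpG range of the erythroid ones (Fisher's exact test, one-sided, p = 0.012), and labels permuted within 3 bins of CpG ratio (permutation test, one-sided, p = 0.031). In the lowest bin 1 of 4 hepatic and 0 of 4 erythroid factors were marked, so the contrast within bins rests mainly on the 3 erythroid factors of the other bins (1 marked), and the whole erythroid list was marked as often as CpG-matched lists (6 of 31, ratio 1.01). With 6 of 9 factors of blood progenitors and myeloid cells marked too, these genes are too few to decide on blood cells as the source, marking in the hepatocytes was not tested, and the single group gives no test of a biological explanation.

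Under the rule of 50% of the peak's length, 36.1% of replicate 1 peaks and 40.4% of replicate 2 peaks were shared, and at an overlap of 1 bp 46.1% and 52.0%. Counting noise at weak calls may account for part of the unshared peaks, since 93.5% of the strongest decile of replicate 1 peaks but 18.2% of the weakest were shared. Broad domains split differently by the peak caller may account for part as well, since 68.5% of the 80701 unshared replicate 1 peaks lay within 3 kb of a replicate 2 peak, against 12.5% of shifted positions. That share includes peaks that overlapped a replicate 2 peak over less than 50% of their length. Weak calls in the same enriched regions would also lie close, so closeness does not single out split domains. Both explanations stay open, and the share due to each was not separated. No biological explanation was tested, as both replicates belong to the same group.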
